A study of Homo sapiens with 12 samples.

How the data were processed

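Gene expression was measured by sequencing of poly(A)-selected RNA from HEK293 cells, a human embryonic kidney line, in 12 libraries. Per the labels' protocols, cells were transduced on day 1, received interferon gamma (IFN-gamma) on day 2 where the group had it, and were harvested on day 4. The titles and treatment labels gave 4 groups of 3 libraries: vector (replicates 1 to 3), A197-270 (4 to 6), vector with IFN-gamma (7 to 9) and A197-270 with IFN-gamma (10 to 12). What A197-270 encodes is not said in the labels. The labels give each sample a number of its own from 1 to 12, so no samples were paired. They do not say that the replicates came from separate cultures, so all p-values measure the spread between these samples, which may be technical.

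The authors deposited a table of normalized values for 19836 protein-coding genes, treated here as a signal: read counts divided by 1 factor per library. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.3b, DESeq2 1.22.1 and the genome build hg38, with no roles, and the annotation release is not given in the sources used here. In each column, 100% of the values were whole multiples, within 0.001 of a read, of the smallest value above 0, so the whole reads could be recovered. Median-of-ratios factors computed on those reads differed from the factors found this way by at most 4.55e-15. The recovered totals ran from 31417431 to 70746868 reads per library. A gene at 0 in all libraries of a group was given a floor of 3 reads over that group, and folds against such a group are lower bounds. Floors, count ratios and their 95% intervals cover counting error only, since the reads carry no molecular identifiers.

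Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend and all 12 libraries in 1 model of 4 group means. The 14049 genes with a mean of at least 10 over all libraries were tested. Reads on the remaining rows made up 0.0179% of the total. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and errors beside them are standard errors (SE). The comparisons were A197-270 against vector without and with IFN-gamma, IFN-gamma against none in each arm, and the interaction, which is the IFN-gamma response of A197-270 cells minus that of vector cells.

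A total of 21 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Members were also counted after being adjusted over the list alone. Of the list calls over the 5 comparisons, 47 were made at the preset correlation and 17 with an estimated correlation. Putting genes with a group at 0 at their lower bound moved no list median by more than 0.021 on the log2 scale. The lists covered IFN-gamma response genes, type I interferon-stimulated genes, MHC class I and class II presentation, NF-kappaB targets, inflammasome and pyroptosis genes, the ER unfolded protein response, ATF4 targets, cytosolic heat shock chaperones, autophagy, constitutive proteasome subunits, complement, p53 targets, proliferation, immediate-early genes, NRF2 targets, cholesterol synthesis, hypoxia and glycolysis, mitochondrially encoded genes, replication-dependent histones and markers of other cell types.

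The genes named in the text were set by a rule fixed at the same time. It took a set of fixed genes. It took, for each comparison of 2 groups, the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, a mean of at least 50 and no overlap between the 6 libraries, a separation that chance gives to 10% of unchanged genes. It took up to 4 called members per list with the largest changes, or 2 members with the highest mean where none was called, and the 8 interaction genes with the smallest adjusted p in each direction. Clone-based names were not counted as gene symbols. Genes chosen after their values were seen are marked as such. Some genes that the rule took are not reported here.

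Gene positions are from the GENCODE 29 annotation of GRCh38, the assembly also called hg38. Of the 19836 identifiers, 19804 matched it without their version suffix, as did all 216 of the named genes. The deposited table does not say how reads shared by near-identical or overlapping genes were assigned, nor whether strand was used. Values of HSPA1A and HSPA1B, C4A and C4B, the HLA genes, the growth hormone cluster, IFNL2 and IFNL3, histone genes and read-through genes are therefore uncertain.

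The fit was tested on simulated counts for the same 14049 genes, with 200 genes changed in the A197-270 group. For A197-270 against vector without IFN-gamma, limma called 80.6% of those changed 1.5-fold, 82.1% at 2-fold and 93.9% at 4-fold, and 3.93% of its calls were false. For the interaction in the same simulation it called 68.7%, 77.6% and 90.9%. With the change placed in the A197-270 group with IFN-gamma, the comparison with its vector group recovered 74.6%, 82.1% and 95.5%, and 9.68% of calls were false. The interaction then recovered 59.7%, 73.1% and 92.4%, and 6.25% of calls were false. In the camera test on simulated data the shifted list was called and 0 of 20 other lists were. Genes were simulated independently of each other, so this does not show how camera does with correlated genes.

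Alternatives were other pseudocounts and filters, libraries scaled to equal totals, quantile normalization, own median-of-ratios factors, only the groups compared, other variance models, array weights, and count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. On those reads edgeR called 3533, 4812, 2291, 1026 and 125 genes in the 5 comparisons, in the order given above. Further alternatives were a 2-fold threshold, an estimated correlation and the fry test for lists, and each replicate left out in turn. Of these, leaving out the 2 deepest libraries, recounting every 2-fold count and recounting lists under equal totals were added after seeing the data. No library was left out of the main comparisons.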

Results

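Poly(A) RNA was measured in HEK293 cells, an established human embryonic kidney line, in 4 groups of 3 libraries. Cells carried either a vector or the construct that the labels call A197-270, each without or with IFN-gamma, a cytokine that acts through the kinases JAK1 and JAK2. What A197-270 encodes is not said in the labels. The series' title concerns the complement membrane attack complex, protein homeostasis and alarmins, and C9, the pore-forming complement component, had 0 reads in all 12 libraries, as did IFNG.

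Library depths ranged from 31417431 to 70746868 reads. The vector libraries 1, 2 and 3 had 32547177, 39759141 and 68558742 reads and the A197-270 libraries 4, 5 and 6 had 43604452, 70746868 and 39180809. With IFN-gamma, the vector libraries 7, 8 and 9 had 36748000, 31417431 and 31757950 reads and the A197-270 libraries 10, 11 and 12 had 34514551, 33943705 and 39299762. Correlations between libraries over the tested genes were 0.978 to 0.987 within a group and 0.953 to 0.978 between groups, across genes, which are not independent replicates. No pair of replicates was alike within sampling noise, with a chi-square per degree of freedom of 5.72 to 17.1. The first principal component held 33.8% of the variance and the second 13.1%. Mitochondrially encoded genes took 0.355% to 0.480% of the reads in vector libraries, 0.546% to 0.802% in A197-270 libraries, 0.405% to 0.475% in vector libraries with IFN-gamma and 0.478% to 0.712% in A197-270 libraries with IFN-gamma.

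The first comparison asked how the transcripts of A197-270 cells differed from those of vector cells without IFN-gamma. Most tested interferon-induced genes were lower in A197-270 cells, and a set of heat shock genes was higher. OAS1 (ENSG00000089127.12, chromosome 12, 112906777 to 112933222 in hg38), an interferon-induced sensor of double-stranded RNA, had 1367 ± 109 normalized counts in vector cells and 5.31 ± 5.66 in A197-270 cells (SD, n = 3 each), a log2 fold change of -8.38 ± 0.583 SE (limma adjusted p = 1.22e-07). HSPA6 (ENSG00000173110.7, chromosome 1, 161524540 to 161526910), a stress-inducible HSP70 chaperone, went the other way, from 21.3 ± 2.98 to 7590 ± 265 normalized counts, a 343-fold rise (log2 8.42 ± 0.101 SE, adjusted p = 2.92e-16). GH1, the pituitary growth hormone gene (ENSG00000259384.6, chromosome 17, 63917200 to 63918838), had 10560 ± 464 normalized counts in vector cells and 1.33 ± 1.15 in A197-270 cells (log2 -12.31 ± 0.307 SE, adjusted p = 5.99e-13).

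All 35 tested type I interferon-stimulated genes fell with A197-270, also when adjusted over the list alone, with a median log2 fold change of -4.17 (camera adjusted p = 4.39e-50). Besides OAS1, RSAD2, which makes an antiviral nucleotide, had a log2 fold change of -7.71 and MX2, a GTPase active against viruses, one of -7.23. XAF1 averaged 159 normalized counts in vector cells and was at 0 in all 3 A197-270 libraries. Of 45 IFN-gamma response genes, 34 fell, 1 rose and 10 did not pass (35 and 1 when adjusted over the list alone, median -1.76, camera adjusted p = 5.31e-28). The chemokine gene CXCL10 fell by 6.79 on the log2 scale, and IRF1, a transcription factor induced by interferons, fell from 391 ± 17.2 to 245 ± 16.5 normalized counts (log2 -0.67, adjusted p = 2.39e-06). In MHC class I presentation 15 of 22 genes fell and 0 rose (17 when adjusted over the list alone, camera adjusted p = 2.45e-13), among them the light chain gene B2M (-1.63) and the peptide transporter gene TAP1 (-1.58). The interferon lambda gene IFNL1 averaged 129 normalized counts in vector cells and had 0 reads in A197-270 cells, at least 160-fold lower.

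Of 34 NF-kappaB targets, 10 fell, 3 rose and 21 did not pass (10 and 3 when adjusted over the list alone, camera adjusted p = 0.000944). The chemokine gene CCL5 fell by 5.93, CXCL8 by 1.37 and NFKBIA, the inhibitor of NF-kappaB, by 0.78. The list calls for NF-kappaB, type I, IFN-gamma and MHC class I genes also passed with an estimated correlation. Of 16 complement genes, 3 fell and 2 rose (3 and 2 when adjusted over the list alone, 6 and 2 under equal totals, 2 and 2 under quantile normalization, camera adjusted p = 0.228), and the regulator gene SERPING1 (-1.32) was among those that fell. Of 16 MHC class II genes 3 fell and 1 rose (3 and 2 when adjusted over the list alone, camera adjusted p = 0.121). In the inflammasome list 1 of 6 genes fell (1 when adjusted over the list alone, camera adjusted p = 0.179), which was TXNIP, a regulator of thioredoxin and glucose uptake (-1.18).

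Among 22 cytosolic heat shock chaperones, 13 rose, 3 fell and 6 did not pass (14 and 3 when adjusted over the list alone, 9 and 4 under quantile normalization). Their camera adjusted p was 9.62e-06, and adjusted p = 0.246 with an estimated correlation. CRYAB, a small heat shock protein gene, rose 8.40-fold (log2 3.07), the HSP40 gene DNAJB1 rose 2.76-fold (1.46), and the co-chaperone gene BAG3 rose 2.24-fold (1.16). In the ER unfolded protein response list 2 of 18 genes rose and 1 fell (1 and 1 when adjusted over the list alone, camera adjusted p = 0.861), against 1 and 2 under equal totals and 1 and 4 under quantile normalization. Of 25 ATF4 targets 10 rose and 2 fell (13 and 2 when adjusted over the list alone), with DDIT4 at 0.70 and TRIB3 at 0.63 on the log2 scale, while PPP1R15A fell by 0.61. As a list they had a camera adjusted p of 0.000476, and adjusted p = 0.366 with an estimated correlation. Of 19 hypoxia and glycolysis genes 14 rose and 0 fell (14 when adjusted over the list alone), including the hexokinase gene HK2 (0.81) and NDRG1 (0.71). In the camera test the adjusted p was 5.09e-08, and adjusted p = 0.245 with an estimated correlation. Of 17 cholesterol synthesis genes 11 fell and 0 rose (11 when adjusted over the list alone), such as IDI1 (-0.76) and INSIG1 (-0.68). For the whole list camera gave an adjusted p of 4.2e-05, and adjusted p = 0.34 with an estimated correlation.

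Mitochondrially encoded genes rose in 10 of 13 cases and fell in 0 (10 when adjusted over the list alone, median 0.76), in the libraries where interferon genes were lower and heat shock and glycolysis genes higher. The list test by camera gave adjusted p = 4.2e-05, and adjusted p = 0.366 with an estimated correlation. Of 12 replication-dependent histone genes, whose main transcripts lack a poly(A) tail, 6 fell and 0 rose (7 when adjusted over the list alone, camera adjusted p = 0.055, 0.0445 without vector 1 and 0.0208 without A197-270 4). The mitochondrial list had been fixed as a sign of RNA quality and the histone list as a sign of poly(A) selection. Whether the arms differed in RNA quality or selection was not tested, and the design does not separate this from the construct. Of 20 p53 targets 8 fell and 1 rose (9 and 1 when adjusted over the list alone). Tested together with camera they had an adjusted p of 0.0395, and adjusted p = 0.382 with an estimated correlation. That call was lost without vector 1 (0.062), vector 2 (0.051) or A197-270 6 (0.101). The NRF2 list had 4 of 12 genes up and 1 down (4 and 1 when adjusted over the list alone, camera adjusted p = 0.0629, 0.0304 without A197-270 5), with the heme oxygenase gene HMOX1 at 0.48. For autophagy genes the counts were 2 up and 8 down of 31 (2 and 8 when adjusted over the list alone, 0 and 14 under equal totals, camera adjusted p = 0.223). SQSTM1, the autophagy receptor p62, had 5433 normalized counts in vector and 5116 in A197-270 cells (adjusted p = 0.0798). Constitutive proteasome subunits had 5 up and 2 down of 31, but 4 and 6 under equal totals (5 and 2 when adjusted over the list alone, camera adjusted p = 0.418). Counts adjusted over the list alone follow in parentheses for the other lists. Proliferation genes had 3 up and 5 down of 23 (6 and 5; camera adjusted p = 0.418), immediate-early genes 3 and 1 of 14 (3 and 1; camera adjusted p = 0.412) with MYC at 0.77, and markers of other cell types 1 and 0 of 7 (1 and 0; camera adjusted p = 0.412).

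Over all 14049 tested genes limma called 1756 higher and 1766 lower with A197-270, of which 28 and 150 changed at least 2-fold. With libraries scaled to equal totals the split was 1161 higher and 2741 lower, so the direction of small changes depends on the scaling.

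**Figure D1:**
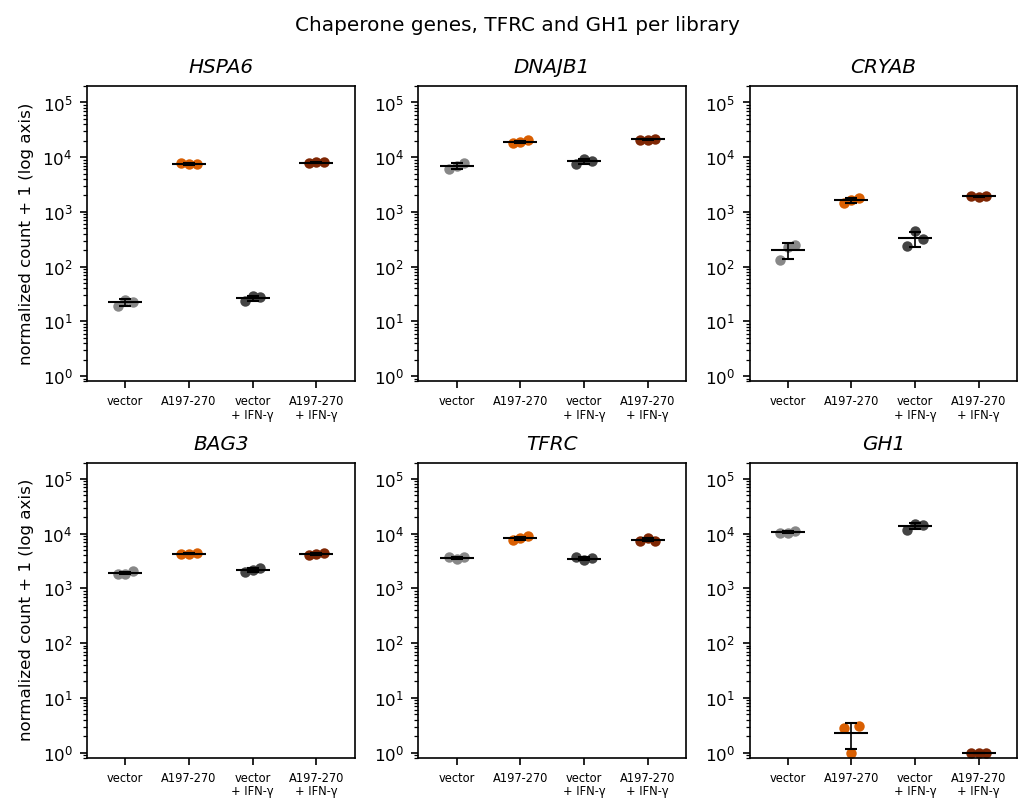
Normalized counts (plus 1, log axis) of HSPA6, DNAJB1, CRYAB, BAG3, TFRC and GH1 in the 4 groups. Points are libraries and bars are means with SD (n = 3); HSPA6 averaged 21.3 and 25.7 in the vector groups and 7590 and 7974 in the A197-270 groups.

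The same construct comparison was made in cells that had received IFN-gamma. The difference in IRF1 did not pass the test, whereas some chemokine and interferon genes were lower in A197-270 cells and 15 of 22 heat shock chaperones were higher. IRF1 had 4573 ± 202 normalized counts in vector and 4188 ± 146 in A197-270 cells (SD, n = 3 each; log2 -0.13, limma adjusted p = 0.12). HSPA6 was 299.7-fold higher (log2 8.23, adjusted p = 4.06e-16), and GH1, at 13780 ± 1693 in vector cells and 0 reads in A197-270 cells, was at least 12050-fold lower. CCL5 fell by 4.18 and the interferon beta gene IFNB1 by 4.14 on the log2 scale.

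In the IFN-gamma list 25 of 45 genes were lower with A197-270, 1 higher and 19 did not pass (26 and 1 when adjusted over the list alone, median -0.38, camera adjusted p = 4.69e-08). Its largest falls were the chemokine genes CXCL11 (-3.45), CXCL9 (-3.01) and CXCL10 (-2.32), and this was the only list of this comparison whose call passed with an estimated correlation. Of 35 type I genes 24 were lower and 1 higher (25 and 1 when adjusted over the list alone, median -0.72, camera adjusted p = 8.51e-10, and adjusted p = 0.249 with an estimated correlation), such as IFI27 (-2.09), MX2 (-1.81) and IFITM3 (-1.69). Of 22 MHC class I genes 7 were lower and 1 higher (7 and 1 when adjusted over the list alone, 11 and 1 under equal totals, 12 and 0 under quantile normalization), with HLA-B at -0.83 and B2M at -0.55. Their camera adjusted p was 0.00508, and adjusted p = 0.214 with an estimated correlation. For NF-kappaB targets 13 of 34 were lower and 2 higher (13 and 2 when adjusted over the list alone), with NFKBIA and RELB both at -0.65. As a list they had a camera adjusted p of 0.00516, and adjusted p = 0.0833 with an estimated correlation. Of 16 complement genes 4 were lower and 2 higher (4 and 2 when adjusted over the list alone, 7 and 2 under equal totals, camera adjusted p = 0.0552, 0.0333 without vector + IFN-gamma 7 and 0.0457 without vector + IFN-gamma 8), with SERPING1 at -0.93.

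Heat shock chaperones were higher in 15 of 22 cases and lower in 1 (17 and 1 when adjusted over the list alone, 10 and 3 under quantile normalization), with CRYAB at 2.57, DNAJB1 at 1.34 and BAG3 at 1.01 on the log2 scale. In the camera test the adjusted p was 2.66e-07, and adjusted p = 0.214 with an estimated correlation. Hypoxia and glycolysis genes were higher in 17 of 19 cases and lower in 0 (17 when adjusted over the list alone), with HK2 at 1.12 and NDRG1 at 1.03. For the whole list camera gave an adjusted p of 1.79e-09, and adjusted p = 0.214 with an estimated correlation. ATF4 targets were higher in 12 of 25 and lower in 2 (13 and 2 when adjusted over the list alone). The list test by camera gave adjusted p = 0.00432, and adjusted p = 0.442 with an estimated correlation. NRF2 targets were higher in 8 of 12 and lower in 1 (9 and 1 when adjusted over the list alone, 4 and 1 under equal totals). Tested together with camera they had an adjusted p of 0.00958, and adjusted p = 0.214 with an estimated correlation. Constitutive proteasome subunits were higher in 11 of 31 and lower in 2 (12 and 2 when adjusted over the list alone), for example PSMB7 (0.50), although their median went from 0.079 to -0.009 under equal totals. Their camera adjusted p was 0.00516, and adjusted p = 0.442 with an estimated correlation. Cholesterol synthesis genes were lower in 10 of 17 and higher in 1 (11 and 1 when adjusted over the list alone), such as IDI1 (-0.75). As a list they had a camera adjusted p of 0.00448, and adjusted p = 0.442 with an estimated correlation. Of 20 p53 targets 11 were lower and 0 higher (11 and 1 when adjusted over the list alone), such as the death receptor gene FAS (-0.53). In the camera test the adjusted p was 0.00122, and adjusted p = 0.249 with an estimated correlation. Mitochondrially encoded genes were higher in 7 of 13 and lower in 0 (8 when adjusted over the list alone). For the whole list camera gave an adjusted p of 0.00789, and adjusted p = 0.555 with an estimated correlation. They rose in the libraries that also had higher heat shock and glycolysis genes, and the call was lost without A197-270 + IFN-gamma 12 (0.0536). A difference in RNA quality between the arms was not tested here either.

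The transferrin receptor gene TFRC was 2.22-fold higher (log2 1.15, adjusted p = 5.37e-08), MYC 1.97-fold (0.98) and C8orf4 9.13-fold (3.19). Autophagy genes were higher in 3 and lower in 9 of 31 (3 and 11 when adjusted over the list alone, 0 and 19 under equal totals, camera adjusted p = 0.0689, 0.0331 without vector + IFN-gamma 7), and the endosomal protein gene ZFYVE21 and the ubiquitin ligase gene RNF34 both fell by 0.25 on the log2 scale (adjusted p = 0.00207 and 0.00051). The ER list had 5 of 18 genes higher and 0 lower (4 when adjusted over the list alone, camera adjusted p = 0.083, 0.0153 without vector + IFN-gamma 8), but 3 and 2 under equal totals. The other lists did not pass: MHC class II had 2 higher and 3 lower (camera adjusted p = 0.388; 3 and 2 under quantile normalization), inflammasome genes 0 and 2 (0.462), proliferation genes 5 and 2 (0.462; 2 and 9 under equal totals), immediate-early genes 3 and 6 (0.462), histones 1 and 3 (0.253; 1 and 5 under equal totals) and markers of other cell types 1 and 1 (0.522). Their counts adjusted over the list alone differed for immediate-early genes, with 4 and 6.

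Over all genes limma called 2616 higher and 2272 lower, 46 and 73 of them at least 2-fold, and under equal totals 1512 and 4170. With and without IFN-gamma, 1412 genes were higher and 1153 lower in both comparisons, against 327 and 286 for independent lists, and 9 went opposite ways. No library was shared between both comparisons, but both used the same estimate of each gene's spread from all 12 libraries. Their calls are therefore not independent, and the numbers for independent lists are no chance level.

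IFN-gamma was then compared with none in vector cells. It raised most of the tested IFN-gamma response and MHC class I genes. IRF1 (ENSG00000125347.13, chromosome 5, 132481609 to 132490798) rose 11.7-fold, from 391 ± 17.2 to 4573 ± 202 normalized counts (SD, n = 3 each; log2 3.55 ± 0.0603 SE, limma adjusted p = 2.1e-14). GBP1, a GTPase of cell-autonomous immunity, rose from 170 to 10193 normalized counts (log2 5.90, adjusted p = 2.98e-13). IDO1, which degrades tryptophan, had 0 reads without IFN-gamma and was at least 202-fold higher with it.

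Of 45 IFN-gamma response genes 43 rose and 0 fell (44 when adjusted over the list alone, median 1.93, camera adjusted p = 3.91e-58). Of 22 MHC class I genes 18 rose and 0 fell (18 when adjusted over the list alone, median 1.44, camera adjusted p = 3.44e-26), with the immunoproteasome gene PSMB9 at 3.82 and TAP1 at 3.35 on the log2 scale. Of 16 complement genes 9 rose and 1 fell (9 and 1 when adjusted over the list alone, camera adjusted p = 1.15e-06), with CFB at 4.73, and of 34 NF-kappaB targets 13 rose and 1 fell (14 and 1; camera adjusted p = 3.81e-05), such as CSF1 (2.00). The calls for these 4 lists also passed with an estimated correlation. Of 35 type I genes 16 rose and 2 fell (19 and 2 when adjusted over the list alone, median 0.60, camera adjusted p = 3.34e-08, and adjusted p = 0.38 with an estimated correlation), with SAMD9L at 3.37 and IFITM3 at 1.96.

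Proliferation genes fell in 8 of 23 cases and rose in 0 (10 when adjusted over the list alone, 4 and 0 under equal totals), including CCNB1 (-0.33) and PLK1 (-0.28). The list test by camera gave adjusted p = 0.00103, and adjusted p = 0.167 with an estimated correlation. Outside the lists, the activin subunit gene INHBA (-0.82) and the zinc finger gene ZNF778 (-0.94) fell. MHC class II genes rose in 3 of 16 cases (5 up and 1 down when adjusted over the list alone). Tested together with camera they had an adjusted p of 0.0433, and adjusted p = 0.365 with an estimated correlation. This call was lost without vector 2 (0.0521), vector 3 (0.0961) or vector + IFN-gamma 7 (0.059). ATF4 targets rose in 6 of 25 and fell in 1 (7 and 1 when adjusted over the list alone). Their camera adjusted p was 0.0433, and adjusted p = 0.741 with an estimated correlation. This call was lost without vector 1 (0.123), vector + IFN-gamma 7 (0.059) or 8 (0.181). Constitutive proteasome subunits fell in 10 of 31 and rose in 2 (10 and 5 when adjusted over the list alone, 5 and 5 under equal totals). As a list they had a camera adjusted p of 0.0465, and adjusted p = 0.741 with an estimated correlation. This call was lost without vector 1 (0.081), vector 2 (0.0741), vector + IFN-gamma 7 (0.195) or 9 (0.086). Hypoxia and glycolysis genes fell in 3 of 19 and rose in 1 (4 and 1 when adjusted over the list alone, 1 and 1 under quantile normalization). In the camera test the adjusted p was 0.0487, and adjusted p = 0.741 with an estimated correlation. This call was lost without vector 2 (0.103), vector 3 (0.0674), vector + IFN-gamma 7 (0.13) or 9 (0.0687).

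The other lists did not pass. Heat shock chaperones had 2 up and 5 down (camera adjusted p = 0.632; 4 and 4 under equal totals, 2 and 2 under quantile normalization), the ER list 1 and 2 (0.632; 2 and 0 under equal totals), inflammasome genes 1 and 0 (0.632), p53 targets 1 and 0 (0.485), immediate-early genes 5 and 2 (0.519; 2 and 1 under quantile normalization), NRF2 targets 1 and 1 (0.82) and markers of other cell types 0 and 1 (0.972). Cholesterol, mitochondrial and histone genes had 0 called members (0.992, 0.547 and 0.675). Autophagy genes had 5 up, with the receptor gene OPTN at 0.47, and 1 down (0.0714, 0.0465 without vector 3 and 0.0477 without vector + IFN-gamma 7). Counts adjusted over the list alone differed for the ER list, with 2 and 2, and markers of other cell types, with 1 and 1. Over all genes limma called 1029 higher and 1376 lower, 131 and 5 of them at least 2-fold, and under equal totals 1526 and 830. The total of 2405 became 1461 without vector 1, 1428 without vector 2 and 1411 without vector + IFN-gamma 9.

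**Figure D2:**
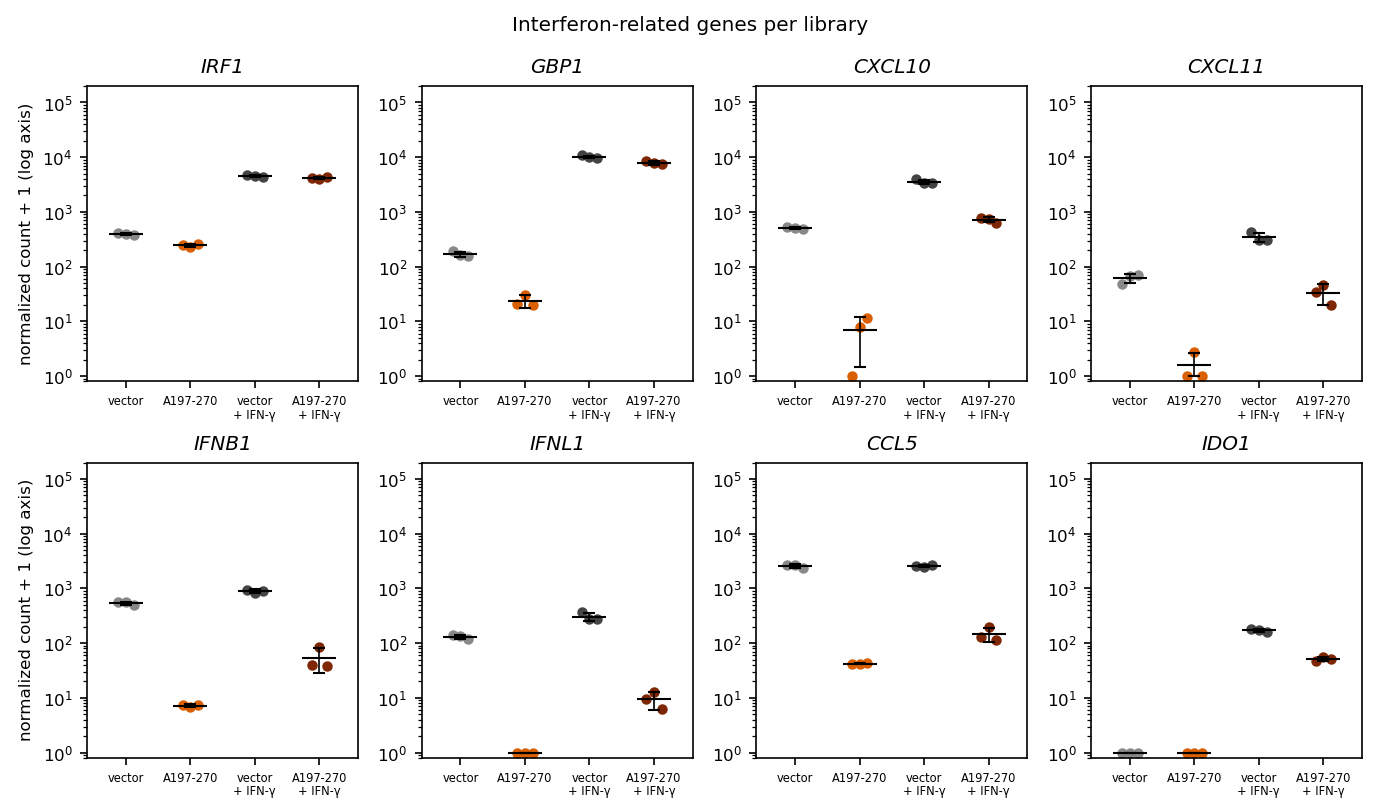
Normalized counts (plus 1, log axis) of IRF1, GBP1, CXCL10, CXCL11, IFNB1, IFNL1, CCL5 and IDO1 in the 4 groups. Points are libraries and bars are means with SD (n = 3); IRF1 averaged 391 in vector and 245 in A197-270 cells without IFN-gamma, and 4573 and 4188 with it.

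In A197-270 cells IFN-gamma raised most of the tested IFN-gamma and type I genes. IRF1 rose 17.0-fold, from 245 ± 16.5 to 4188 ± 146 normalized counts (SD, n = 3 each; log2 4.09, limma adjusted p = 9.41e-16). XAF1, at 0 without IFN-gamma, was at least 1306-fold higher, and GBP1 rose by 8.39 on the log2 scale. Of 45 IFN-gamma response genes 43 rose and 0 fell (44 when adjusted over the list alone, median 3.48, camera adjusted p = 1.88e-95), and of 35 type I genes 34 rose and 0 fell (34; median 3.77, camera adjusted p = 1.99e-74), with OAS1 at 8.42 and RSAD2 at 8.25.

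MHC class I genes rose in 17 of 22 cases (18 when adjusted over the list alone, median 2.01, camera adjusted p = 4.72e-40), with PSMB9 at 5.63 and TAP1 at 4.76, complement genes in 8 of 16 (9 up and 1 down when adjusted over the list alone, camera adjusted p = 3.69e-07), with SERPING1 at 3.84, and NF-kappaB targets in 8 of 34 (10; camera adjusted p = 4.84e-08), with CSF1 at 2.14. In these 3 lists 0 members fell over all genes, and with the interferon lists they made the 5 calls that passed with an estimated correlation. MHC class II genes rose in 3 of 16 and fell in 0 (4 when adjusted over the list alone), with HLA-DRA at 0.77. For the whole list camera gave an adjusted p of 0.000715, and adjusted p = 0.0809 with an estimated correlation. Proliferation genes fell in 7 of 23 and rose in 0 (9 and 1 when adjusted over the list alone), with PLK1 at -0.36. The list test by camera gave adjusted p = 0.000595, and adjusted p = 0.103 with an estimated correlation. ATF4 targets rose in 6 of 25 and fell in 1 (10 and 2 when adjusted over the list alone). Tested together with camera they had an adjusted p of 0.00201, 0.0617 without A197-270 + IFN-gamma 11, and adjusted p = 0.529 with an estimated correlation. In the ER list 1 of 18 genes rose, EDEM1 (0.23; 2 when adjusted over the list alone). The list's camera adjusted p was 0.039, and adjusted p = 0.647 with an estimated correlation. This call was lost without A197-270 4 (0.09), A197-270 5 (0.108), A197-270 + IFN-gamma 10 (0.063) or 11 (0.106).

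The other lists did not pass. Autophagy genes had 3 up and 0 down (camera adjusted p = 0.322), proteasome subunits 3 and 0 (0.633), p53 targets 1 and 2 (0.32; 0.0327 without A197-270 + IFN-gamma 11), heat shock chaperones 1 and 1 (0.661), inflammasome genes 1 and 0 (0.351), NRF2 targets 1 and 0 (0.661), immediate-early genes 0 and 1 (0.239) and histones 1 and 0 (0.0789; 0.0305 without A197-270 4 and 0.0474 without A197-270 + IFN-gamma 12). Cholesterol, hypoxia, mitochondrial and other cell type genes had 0 called members (0.213, 0.229, 0.259 and 0.861). When adjusted over the list alone, counts up and down were 4 and 0 for autophagy, 3 and 1 for proteasome, 2 and 3 for p53, 2 and 0 for hypoxia and 0 and 2 for mitochondrial genes, and as above for the others. The first 3 of these 4 lists passed without single libraries: cholesterol without A197-270 6 (0.0237) or A197-270 + IFN-gamma 11 (0.0418), hypoxia without A197-270 + IFN-gamma 12 (0.0296), and mitochondrial genes without A197-270 4 (0.0202) or A197-270 + IFN-gamma 12 (0.0179). Over all genes limma called 588 higher and 422 lower, 174 and 4 of them at least 2-fold. The split was 617 and 411 under equal totals and 530 and 562 under quantile normalization, where the majority turned. The total of 1010 became 575 without A197-270 4 and 660 without A197-270 + IFN-gamma 11. Between the IFN-gamma comparisons of both arms, which share no library, 381 genes rose and 245 fell in each, against 43.1 and 41.3 for independent lists. Here too the estimate of each gene's spread was shared, so the calls are not independent.

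**Figure D3:**
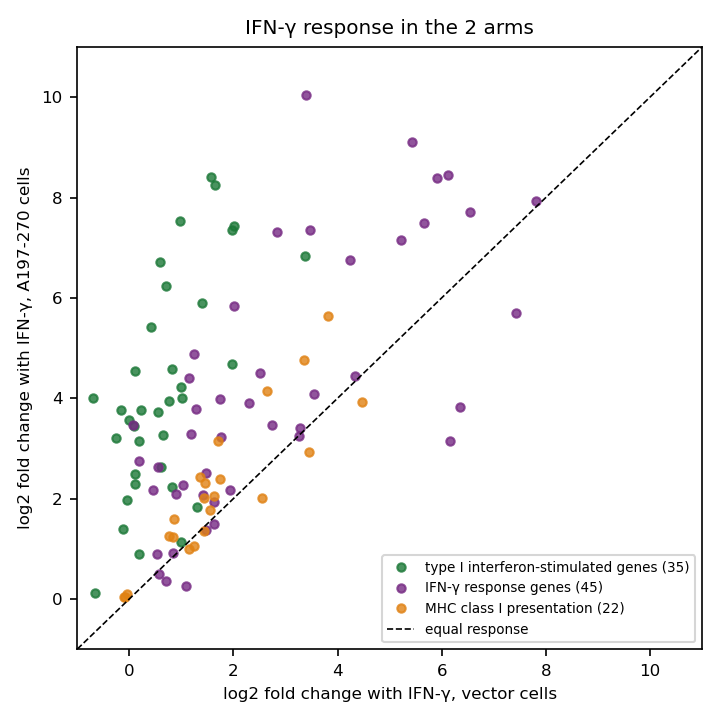
Log2 fold change with IFN-gamma in vector cells (x axis) and A197-270 cells (y axis) for the tested genes of the type I (35), IFN-gamma (45) and MHC class I (22) lists. Points are genes and the dashed line marks equal responses; the median log2 fold changes of the type I list were 0.60 and 3.77.

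Whether the response to IFN-gamma differed between the arms was tested as the interaction. Most of the tested type I genes rose more in A197-270 cells, where all 35 started lower, and 23 of 45 IFN-gamma genes did not pass. PARP9, itself interferon-induced, had an interaction log2 of 3.27 ± 0.0801 SE (limma adjusted p = 6.94e-12; n = 3 per group). XAF1, at 0 in A197-270 cells without IFN-gamma, had one of at least 6.96 (1.31e-11). For IRF1 the interaction was smaller, at 0.54 (0.00278). Of 35 type I genes 32 had a larger response and 0 a smaller one (33 when adjusted over the list alone, median 3.37, camera adjusted p = 1.16e-81), of 45 IFN-gamma genes 22 and 0 (27 and 3; median 1.23, camera adjusted p = 5.02e-27) and of 22 MHC class I genes 12 and 0 (13; median 0.40, camera adjusted p = 9.6e-15). The calls for these 3 lists also passed with an estimated correlation.

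Proteasome subunits had 0 called genes (2 up when adjusted over the list alone, median 0.08). As a list they had a camera adjusted p of 0.000932, and adjusted p = 0.672 with an estimated correlation. Hypoxia and glycolysis genes had 1, NDRG1 (0.32; 5 up when adjusted over the list alone), whose call was lost in 6 of the 12 runs without 1 library. In the camera test the adjusted p was 0.000932, and adjusted p = 0.672 with an estimated correlation. The ER list had 0 (median 0.13; camera adjusted p = 0.0282, and adjusted p = 0.722 with an estimated correlation), and was lost without vector 3 (0.272), A197-270 4 (0.0698) or 5 (0.0818), vector + IFN-gamma 7 (0.159) or 9 (0.0674), or A197-270 + IFN-gamma 11 (0.0659). NF-kappaB targets had 2 up (camera adjusted p = 0.672), among them CCL5 (1.75, adjusted p = 0.000147), and heat shock chaperones 1, DNAJA1 (0.39, adjusted p = 0.00243; camera adjusted p = 0.489). The other 13 lists had 0 called genes and did not pass over all libraries, with camera adjusted p from 0.052 for mitochondrial, 0.0552 for immediate-early and 0.0839 for p53 genes through cholesterol (0.369), autophagy (0.369), histone (0.369), complement (0.459), NRF2 (0.477), MHC class II (0.489), inflammasome (0.703), ATF4 (0.887) and proliferation genes (0.907) to 0.964 for markers of other cell types. When adjusted over the list alone, genes up and down were 2 and 1 for NF-kappaB, 1 and 0 for heat shock, 2 and 1 for complement, 1 and 1 for p53, 0 and 2 for immediate-early and 1 and 0 for NRF2 genes, and 0 for the others and the ER list. Without single libraries 3 of them passed: mitochondrial genes (0.00325 without vector 3, 0.000929 and 0.026 without A197-270 4 and 6, 0.0254 without vector + IFN-gamma 8, 0.00211 without A197-270 + IFN-gamma 12), immediate-early genes (0.0414 without vector 3, 0.0172 without A197-270 5, 0.0451 without vector + IFN-gamma 8, 0.045 without A197-270 + IFN-gamma 11) and p53 targets (0.0307 without A197-270 6, 0.0451 without vector + IFN-gamma 8, 0.00373 without A197-270 + IFN-gamma 11). Over all genes limma called 115 with a larger and 11 with a smaller response, 76 and 1 of them at least 2-fold, and the total of 126 became 229 without vector 3, with 151 larger and 78 smaller. The majority of larger responses thus depends on the libraries in part, with 159 larger and 135 smaller without the 2 deepest ones, a run chosen after seeing the data.

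**Figure D4:**
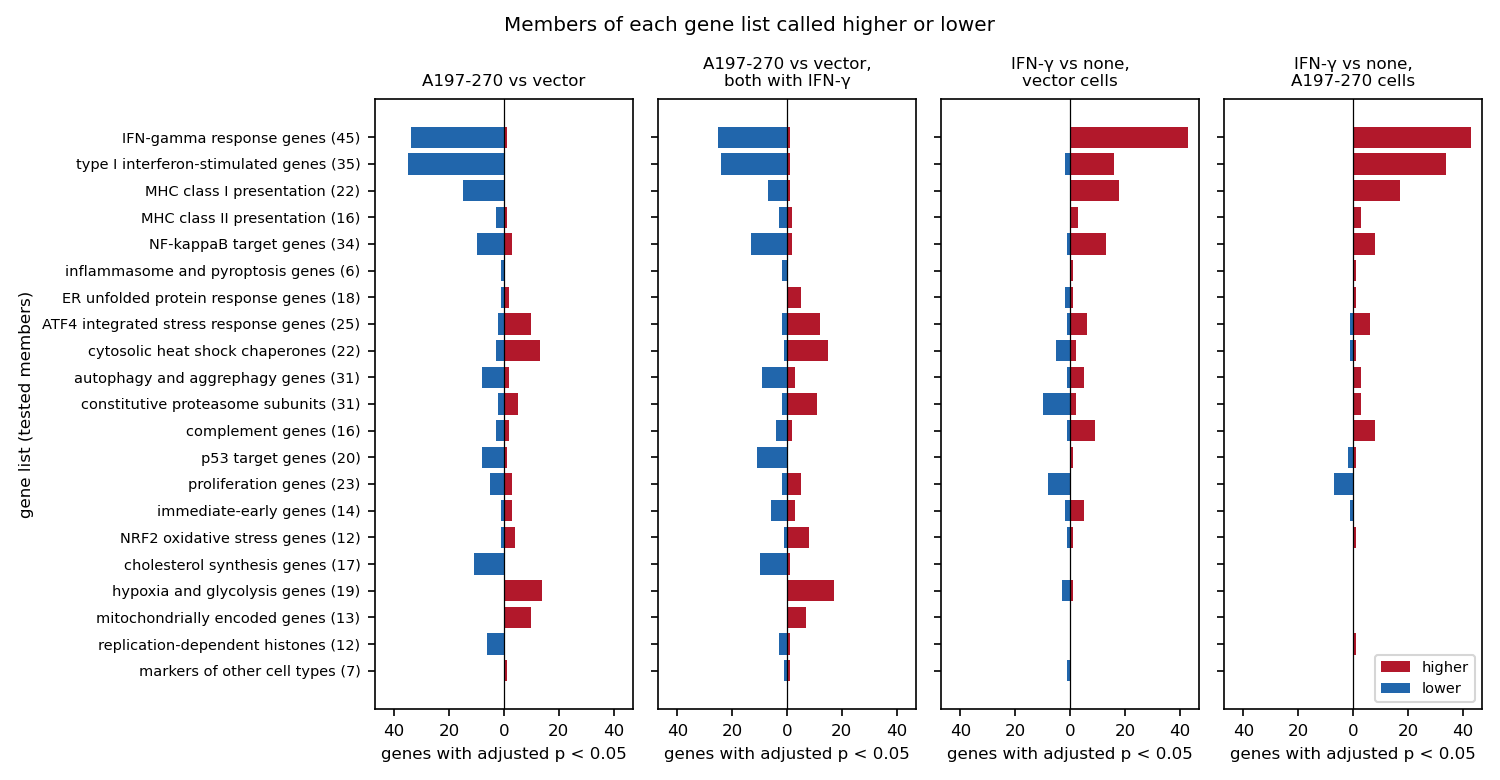
Number of genes called higher and lower (bars, limma adjusted p under 0.05) in each of the 21 lists in the 4 comparisons of 2 groups. Of 35 type I genes, 35 were lower with A197-270 without IFN-gamma and 24 with it.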

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

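The counts over splits of the libraries were planned, and the tests of explanations were chosen after the result was seen. A difference between the IFN-gamma responses of both arms, tested as the interaction with limma, picked out the results listed here. It called 126 genes. Among those with the smallest adjusted p that responded more in A197-270 cells, PARP9 (3.27 on the log2 scale), EPSTI1 (3.25), IFITM1 (3.19), IFIH1 (3.18), UBE2L6 (2.11), LGALS3BP (2.03) and XAF1 are all interferon-induced genes. XAF1 had 0 reads in A197-270 cells without IFN-gamma, so its interaction is only bounded, at 6.96 or more. Responses were lower in A197-270 cells for TNFRSF10D (-0.71), NT5DC2 (-0.60), GPAA1 (-0.60), CLN8 (-0.55), COL18A1 (-0.42), LINGO1 (-0.40), RC3H1 (-0.34) and RIPOR1 (-0.33), and the calls of COL18A1, LINGO1 and RIPOR1 were lost in 9, 5 and 6 of the 12 runs without 1 library. The list medians were 3.37 for type I genes, 1.23 for IFN-gamma genes, 0.40 for MHC class I, 0.18 for hypoxia and glycolysis, 0.13 for the ER list and 0.08 for proteasome subunits. The last 3 lost their calls with an estimated correlation (camera adjusted p = 0.672, 0.722 and 0.672). The ER call was also lost without vector 3 (0.272), A197-270 4 (0.0698) or 5 (0.0818), vector + IFN-gamma 7 (0.159) or 9 (0.0674), or A197-270 + IFN-gamma 11 (0.0659).

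Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 2 called as many genes as the real 126. The other of these 2 called 1025 genes, and the next highest 3. The share is under 0.05 but cannot test the interaction, because random splits put the construct and IFN-gamma effects into the spread within groups. The 99 random splits called a median of 0 genes. The split with 1025 genes kept the 3 vector libraries with IFN-gamma together as 1 group. Its contrast set them against the A197-270 libraries without IFN-gamma, all 3 of which fell in the groups that are subtracted. These lay furthest apart on the first principal component, at 35.4 to 37.7 and -47.6 to -41.3. The calls of that split thus carry the real difference between those groups, and its count is no measure of chance. For the comparisons of 2 groups the 10 splits of 6 libraries are too few for a share under 0.05. Splits other than the real one also mix the 2 groups, which puts their difference into the spread within groups. Their low counts are therefore no measure of chance. In each comparison 1 of 10 splits reached the real count, the real one itself. The counts were 3522 for A197-270 without IFN-gamma (highest other split 1), 4888 with it (2), 2405 for IFN-gamma in vector cells (3) and 1010 in A197-270 cells (1).

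The interaction goes with interferon-induced genes that were already high in vector cells without IFN-gamma. If RNA of IFN-gamma-treated vector cells had been mixed into those libraries, all interferon genes would need about the same share of it, but the median share needed by GBP1 to GBP5 was 1.511% and that needed by the type I list 61.39%, which argues against mixing. In A197-270 cells 43 of 45 IFN-gamma genes rose with IFN-gamma, so these cells could respond to it. This does not bear on the difference in cells without IFN-gamma, where IFNG had 0 reads. A candidate explanation is that vector cells made more type I and type III interferon: IFNB1 was lower in A197-270 cells by a log2 fold change of -6.22, and IFNL1 at least 160-fold. Both genes also rose with IFN-gamma in A197-270 cells, IFNB1 by 2.81 on the log2 scale and IFNL1 at least 10.6-fold. The values therefore do not tell whether less interferon was a cause or a result of lower interferon signalling. With IFN-gamma, IFNB1 still had a log2 fold change of -4.14, while the type I list had a median of -0.72. The explanation was found and tested on the same data. Whether the difference came from the construct or from how each arm was prepared was not tested.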

How the results depend on the processing

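The runs without the 2 deepest libraries, the recounts at 2-fold and the recounts of lists under equal totals were chosen after seeing the data, and the others were planned. The counts of genes called stayed within 1.5 times of the main count in every setting but those named here. Requiring a 2-fold change left 178 genes for A197-270 against vector without IFN-gamma and 119 with it, 136 for IFN-gamma in vector cells, 178 in A197-270 cells and 77 for the interaction, by construction. With array weights, IFN-gamma changed 4438 genes in vector cells and the interaction called 421, with 270 larger and 151 smaller responses. The interaction called 283 genes with DESeq2 on whole reads (221 and 62) and 294 without the 2 deepest libraries (159 and 135), against 115 and 11 of the main 126. For the array weights, DESeq2 and the depth the cause was not tested. In the simulations of the interaction, 12.1% of DESeq2's calls and 3.07% of limma's were false with the change placed in A197-270 cells without IFN-gamma, and 11.4% and 6.25% with it placed in those with IFN-gamma. Of the 2-fold counts, A197-270 with IFN-gamma gave 204 with no filter and 63 with a mean of at least 50, since more and fewer genes were tested, and IFN-gamma in vector cells gave 222 with array weights. Leaving out 1 replicate at a time gave 2587 to 3227 genes for A197-270 without IFN-gamma, 3695 to 4411 with it, 1411 to 2545 for IFN-gamma in vector cells, 575 to 887 in A197-270 cells and 103 to 229 for the interaction. The same runs gave 161 to 183, 103 to 130, 122 to 149, 167 to 184 and 69 to 81 genes at 2-fold or more, and 43 to 51 list calls. With an estimated correlation 17 of the 47 list calls remained. The calls of 2 named genes reversed, both under quantile normalization, where JUN had a log2 fold change of -0.069 for A197-270 without IFN-gamma and HSPD1 one of 0.0060 for IFN-gamma in vector cells. No list call reversed in any setting run on the lists. In the runs without 1 replicate, counting each call once per run, calls of named genes were lost 260 times and list calls 29 times. Calls were gained 4 and 29 times, and 2736 and 698 outcomes stayed the same. The same call can be lost in several runs, so these are not numbers of separate calls. Own median-of-ratios factors moved nothing, because they match the authors' factors, and so this says nothing about stability. Depth limits low genes: 3 reads over a group correspond to 0.804 to 1.16 normalized counts.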

Other observations

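All tests of explanations in this part were chosen after the result was seen, and so were the genes named here outside the rule. The interferon genes themselves differed between the arms. IFNB1 (chromosome 9, 21077105 to 21077963 in hg38) had 538 ± 37.1 normalized counts in vector cells and 6.24 ± 0.371 in A197-270 cells, and 898 ± 59.7 and 53.4 ± 25.9 with IFN-gamma (SD, n = 3). IFNL1 had 129 ± 11.3 and 0 without IFN-gamma and 305 ± 51.5 and 8.55 ± 3.43 with it. IFNL2 and IFNL3, near-identical copies that share reads, had 0 reads in the A197-270 libraries without IFN-gamma.

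Mitochondrially encoded transcripts did not move as 1 unit. MT-CYB was 2.65-fold higher in A197-270 cells without IFN-gamma (log2 1.41, limma adjusted p = 1.43e-05), while MT-ND1 had a log2 fold change of -0.18 (adjusted p = 0.383). TFRC had 3666 normalized counts in vector cells, 8253 in A197-270 cells, and 3514 and 7813 with IFN-gamma.

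With IFN-gamma, the chemokine genes CXCL9, CXCL10 and CXCL11 had lower levels in A197-270 cells. The response to IFN-gamma was not lower for CXCL10, which rose by 7.31 on the log2 scale in A197-270 cells and by 2.84 in vector cells (interaction 4.47, limma adjusted p = 0.0145). CXCL11 rose by 4.50 and 2.51 (interaction adjusted p = 0.186). CXCL9 went from 0 reads in both arms to 74.0 normalized counts in vector cells and 8.29 in A197-270 cells. As both arms started at 0, its interaction equals the difference with IFN-gamma, a log2 fold change of -3.01. In limma this passed as the difference with IFN-gamma (SE 0.705, adjusted p = 0.00471). It did not pass as the interaction, which has a larger SE (0.997, adjusted p = 0.245).

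Of 22 heat shock chaperones 13 were higher and 3 lower in A197-270 cells without IFN-gamma, and 15 and 1 with it (9 and 4, and 10 and 3, under quantile normalization). HSPA6, outside the list, was 343-fold and 299.7-fold higher. Reads taken from the copies HSPA1A and HSPA1B would give HSPA6 the same share of their reads in both arms, but it was 15.41% or more in every A197-270 library and 0.107% or less in every vector library. A general rise of stress genes including the ER stays open. The share of higher ER genes set as its sign was not reached with or without IFN-gamma. In the ER list 5 of 18 genes were higher with IFN-gamma and 2 without, against 2616 and 1756 of all 14049 tested genes. The list's camera adjusted p was 0.083 with IFN-gamma and 0.861 without. Members of other stress lists were higher in the same comparisons: 17 and 14 of 19 hypoxia and glycolysis genes, 12 and 10 of 25 ATF4 targets and 8 and 4 of 12 NRF2 targets. The NRF2 list did not pass without IFN-gamma (camera adjusted p = 0.0629), and with an estimated correlation 0 of these 3 lists and of the heat shock list passed in either comparison (adjusted p from 0.214 to 0.442). Handling of the A197-270 cultures apart from the construct, which the design does not separate from the arm, was not tested, and neither was a response of the cells to the construct's product. Both stay open.

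GH1 reads were nearly confined to the vector libraries, and with IFN-gamma GH1 was at least 12050-fold lower in A197-270 cells, where it had 0 reads. A plasmid backbone in 1 arm that holds a GH1 part could give this, and the construct maps and read coverage that would test it are not used here. The labels name a Flag vector and an A197-270 plasmid and do not say that their backbones match. A difference in backbone would apply to every comparison of A197-270 with vector. Transcription of the growth hormone locus is the other explanation. Counts were summed over 6 neighbours and copies, in libraries with and without IFN-gamma together. The net excess in vector over A197-270 libraries was 0.0582% of the GH1 counts. Genes that were lower in vector libraries reduce this net value. Of the 6, 1 had a mean high enough to be tested, SCN4A (log2 0.27, limma adjusted p = 0.27), and the copies CSH2 and CSHL1 had 12 and 19 reads in vector cells without IFN-gamma and 0 in A197-270 cells. The annotated span of CSHL1 (63909597 to 63918838) contains that of GH1, so reads given to CSHL1 could be GH1 reads. An isolated activation of GH1 stays possible. These cannot be told apart without the construct sequences.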
